A study of Populus trichocarpa with 18 samples.

How the data were processed

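RNA-seq was carried out on protoplasts of Populus trichocarpa isolated from stem-differentiating xylem and transfected by the polyethylene glycol method. Per the labels, the protoplasts received PtrSND1-B1 together with sGFP, or sGFP alone as the control, and were sampled at 7, 12 and 25 h. The 18 libraries form 6 groups of 3, and each library was assigned to its group and replicate number from its title. The deposited file holds raw counts, as whole numbers of reads per gene model with a column per library. TopHat and edgeR are named in the submitters' processing notes, without a role or a version. The genome build, the annotation, the counting tool, the strandedness of the kit and the treatment of reads that map to several places are not given in the sources used here. Counts of genes that share reads with a close copy, of overlapping genes and of antisense partners are therefore uncertain.

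The file has 45033 models of 40668 loci, and 3063 loci have more than 1 model. Of the 4365 models beyond the first of a locus, 2642 (60.5%) held the same values as the first model in all 18 libraries, so the same reads were counted repeatedly. Only the first model of each locus was used. This choice was made after the file was seen, and all models as separate rows were tried as an alternative added later. Models beyond the first held 13.7 to 17% of a library's counts. The first models held 2690853 to 13970708 counts per library, of which the 10 most abundant took 2.69 to 6.42%, and 3469 first models had 0 counts throughout. No columns were identical. The chi-square per degree of freedom between libraries of a group, over models with at least 20 reads in both together, was 5.88 to 46.8, so no library was treated as a repeat of another. Sequencing reads without molecular identifiers are not independent molecules, so counting intervals cover counting error only.

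Counts were analysed with edgeR 4.0.16 in R 4.3.3. Models were kept by filterByExpr with the 6 groups, which left 23777, and libraries were scaled by TMM with factors of 0.797 to 1.09. A quasi-likelihood negative binomial model with a mean per group was fitted to all 18 libraries, with 12 residual degrees of freedom. The contrasts were PtrSND1-B1 against sGFP at each time and as the mean of the 3 times, the differences of that effect between times, and the differences between times in sGFP protoplasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values quoted come from this edgeR test unless another tool is named. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. CPM values were computed with TMM-scaled library sizes. Overlaps of calls were tested with a one-sided Fisher's exact test. Small sets of pairs were compared by exact permutation, two-sided.

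Libraries of both constructs carry the replicate numbers 1 to 3, and the labels do not say that a number marks a shared batch. Each library's deviation from its group mean was therefore correlated with that of the other libraries, over log2 CPM with a prior count of 2. The 9 pairs with the same number and time had correlations of 0.345 to 0.752 (median 0.658), all over the 0.1 set for pairing. Pairs of the same time with different numbers had a median of -0.312. Deviations cancel within a group, so high correlations with the own number force low ones with the other numbers. This negative median is therefore no separate evidence of pairing. All 18 libraries correlated best with the library of their own number. The numbers were therefore treated as pairing the libraries, from the data and not from the labels. Pairs of the same number at different times had correlations of 0.041 to 0.658 (median 0.354), and 32 of 36 were over 0.1. Pairing across times, which the number block and the exchanges of times inside numbers rely on, is thus less even. Blocked values come from a fit with the replicate number as an additive term, planned before the data were examined (10 residual degrees of freedom), and from a fit with a term for each of the 9 pairs of a time and number (6 residual degrees of freedom). The second, called the paired fit, was added after seeing the data, and an exploratory run had already shown its calls. It cannot be used for differences between times in sGFP protoplasts.

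The fits were tested on simulated counts for PtrSND1-B1 against sGFP at 7 h, with 200 genes changed and 23542 genes tested. Counts were drawn from the mean of each pair of libraries, the library sizes and the dispersions of the paired fit described above. They therefore follow the paired model, so a higher recovery by the paired fit is built in. Without a block the test recovered 15% of the genes changed 2-fold and 49% of those changed 4-fold. With the replicate number as a block it recovered 36% and 71%, and the paired fit recovered 74% and 91%. False calls at 7 h numbered 0 without a block, 0 with the number block and 16 in the paired fit. At 25 h, where nothing was changed, the paired fit gave 4 false calls and the other fits 0.

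Identifiers were looked up in a RefSeq gene table of assembly P.trichocarpa_v4.1, of which 0 loci matched, and the file does not pair identifiers with names. None of the 32 gene lists fixed before the data were examined (among them monolignol, cellulose and xylan synthesis, laccases, transcription factor families, stress genes and markers of phloem, cambium and green cells) therefore had members, and the planned camera tests of these lists were not run. The rule for named genes, fixed beforehand, was the largest changes per contrast among called genes with a mean log2 CPM of at least 1 and no overlap between the groups' libraries, plus the transfected gene, with at most 2 identifiers per direction where names were missing. After values had been seen this was narrowed to the largest rise at 7 h, the largest at 12 h and the 2 largest falls from 7 to 25 h in sGFP protoplasts. The 3 paralogs of PtrSND1-B1 named in the rule could not be looked up and are not analysed here. POPTR_0014s10060.1 was taken as PtrSND1-B1 from the locus known for it in the literature and from its rise after transfection.

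Alternatives were other scaling (RLE, or library size alone), other low-count filters (any model with 1 read, or at least 10 reads in each library of a group), the likelihood ratio test, DESeq2 1.42.0, a 2-fold minimum, only the groups of a contrast in the fit, and the omission of each library in turn. Those for the paired fit were added after seeing the data. Sample labels were regrouped up to 100 times per result with fixed seeds, and all libraries were thinned 5 times to 2690853 counts to test for depth.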

Results

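The libraries measured the transcriptome of Populus trichocarpa (black cottonwood) protoplasts made from stem-differentiating xylem, the tissue in which young wood cells thicken their walls. The question was which transcripts change when PtrSND1-B1, a NAC-domain transcription factor of the group that regulates secondary wall formation, is overexpressed in these cells. PtrSND1-B1 was transfected with sGFP, a green fluorescent protein, and the control received sGFP alone. Each construct was sampled at 7, 12 and 25 h after transfection in 3 libraries, 18 in all. The total count over the first model of each locus was 3541698 to 5454419 per library for sGFP at 7 h, 4746555 to 9107896 at 12 h and 2736863 to 13970708 at 25 h. For PtrSND1-B1 it was 4563708 to 6625569, 3478889 to 5976872 and 2690853 to 5123980 at the same times. The labels do not say whether libraries of a group came from separate plants or protoplast isolations, so p-values measure only the spread between these libraries, which may be technical.

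The transfected gene was examined first. POPTR_0014s10060.1 was taken as PtrSND1-B1 partly from its rise after transfection, because the file does not pair identifiers with names, so it is no independent check of the labels. It was higher in each of the 9 libraries transfected with PtrSND1-B1 than in any of the 9 sGFP libraries. Its level at 7 h was 2250 ± 1000 CPM (SD, n = 3) against 6.36 ± 3.5 CPM in sGFP protoplasts, a log2 fold change of 8.47 (SE 0.72, edgeR adjusted p = 7.12e-05). At 12 h it was 1320 ± 747 CPM against 5.69 ± 2.91 CPM, a log2 fold change of 7.83 (SE 0.698, edgeR adjusted p = 0.000141). At 25 h it was 912 ± 602 CPM against 2.43 ± 0.579 CPM, a log2 fold change of 8.61 (SE 0.739, edgeR adjusted p = 8.33e-05). POPTR_0014s10060.1 had the largest log2 fold change of all 23777 genes tested at each of the 3 times in the fit without a block. Reads from the plasmid and from the chromosomal copy were not separated. In PtrSND1-B1 libraries its level was lower at 25 h than at 7 h in each replicate number, by 1.43 ± 0.347 on the log2 scale (SD, n = 3 numbers). The exact permutation p was 0.00926 (two-sided) over 216 exchanges of the 3 times inside numbers, a test chosen after the values were seen, and 0.2 for 3 against 3 libraries without regard to number. Without PtrSND1-B1 25 h replicate 1 the log2 fold change at 25 h was 7.95. In sGFP protoplasts the change of POPTR_0014s10060.1 from 7 to 25 h was -1.44 on the log2 scale (SE 0.65, edgeR adjusted p = 0.14), and -1.51 (SE 0.494, adjusted p = 0.0306) with the replicate number as a block. With only the libraries of 1 time in the fit, the adjusted p of the rise was 0.115 at 12 h and 0.0514 at 25 h.

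**Figure D1:**
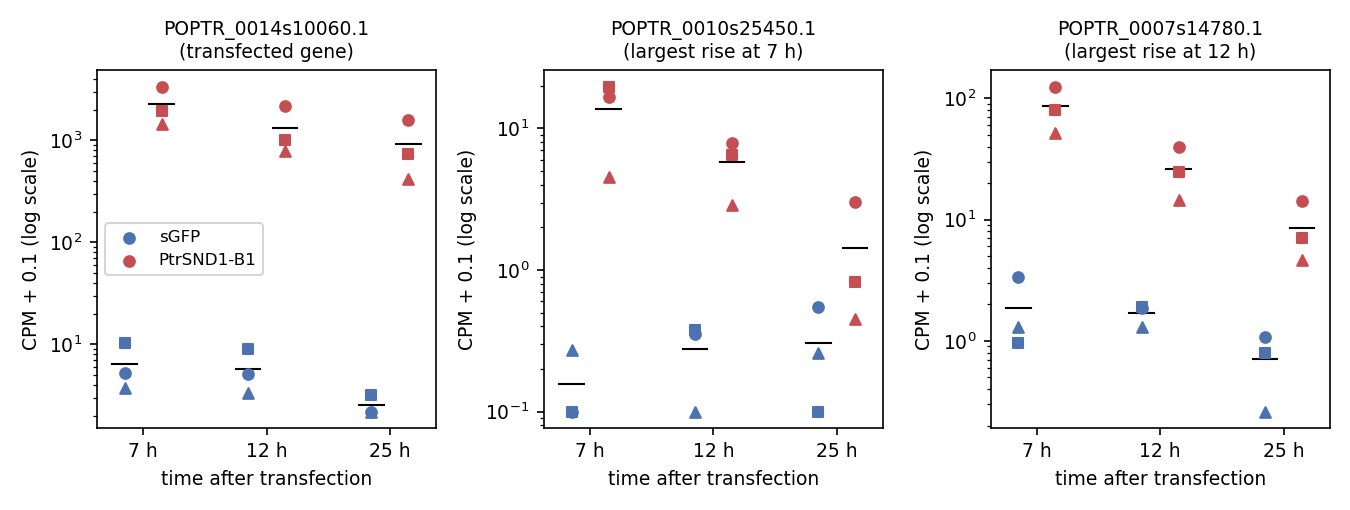
CPM plus 0.1 on a log axis in each library for the transfected gene and the 2 other named genes that rose, at 7, 12 and 25 h after transfection (blue, sGFP; red, PtrSND1-B1; circle, square and triangle, replicates 1, 2 and 3; bar, group mean). POPTR_0014s10060.1 averaged 2250, 1320 and 912 CPM in PtrSND1-B1 libraries and at most 6.36 CPM in sGFP libraries.

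The libraries differed mainly by time and by replicate number. The first principal component of log2 CPM held 36.8% of the variance, and time accounted for 97.5% of the differences along it. The second held 19.1%, and the replicate number accounted for 95.4% of it. The construct accounted for 0.0539% of the first component, 0.817% of the second and 4.43% of the third, which held 12.5% of the variance. The common coefficient of variation between libraries was 29% without a block, 19.2% with the replicate number as a block and 7.9% in the paired fit, in which PtrSND1-B1 and sGFP libraries of the same time and number are compared. Values of both blocked fits are given beside the others because they moved nearly all counts of called genes.

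**Figure D2:**
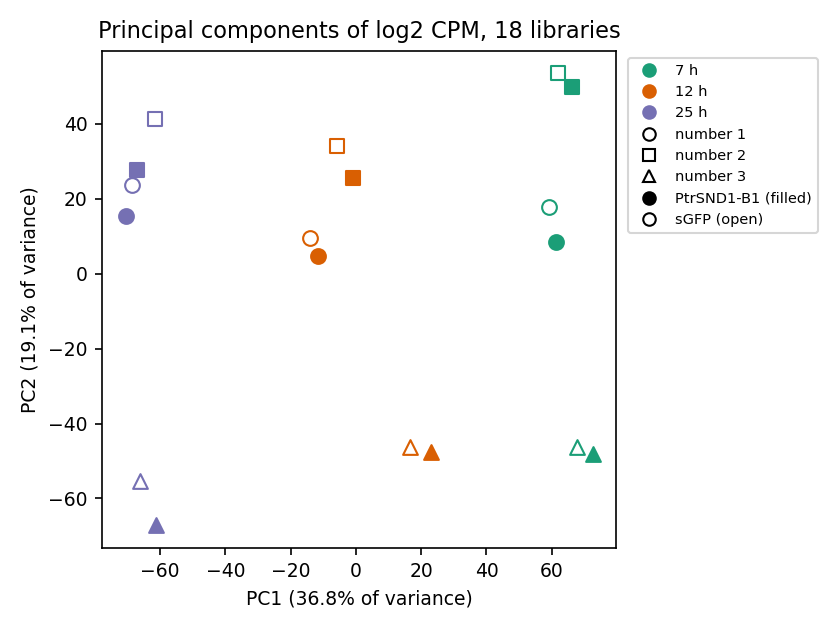
First and second principal components of log2 CPM for the 18 libraries, with 36.8% and 19.1% of the variance (colour, time; symbol, replicate number; filled, PtrSND1-B1; open, sGFP). Libraries separate by time along the first axis and by replicate number along the second, and the 2 libraries of the same time and number lie near each other.

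At 7 h, PtrSND1-B1 protoplasts had higher transcript levels of 14 genes and lower levels of 0, by edgeR's quasi-likelihood test. Besides the transfected gene, 13 genes rose, by 1.25 to 7.19 on the log2 scale (median 4.41). The largest of these rises was that of POPTR_0010s25450.1, from 0.057 ± 0.0987 to 13.6 ± 8.04 CPM (SD, n = 3, edgeR adjusted p = 0.012). Its sGFP libraries held 1 read in all and its PtrSND1-B1 libraries 227, a ratio of 180 after scaling with a 95% counting interval of 32.1 to 7160. POPTR_0007s14780.1 rose from 1.78 ± 1.31 to 85.6 ± 36.6 CPM, a log2 fold change of 5.66 (SE 0.579, edgeR adjusted p = 0.000493), and of 6.33 without sGFP replicate 1. With the replicate number as a block, 51 genes were higher and 17 lower. In the paired fit 370 were higher and 442 lower, among them all 14 genes called without a block. This total became 470, 248 or 349 without the replicate 1, 2 or 3 pair, and 1539 without the low-count filter. The paired changes were mostly small, with a median of 0.635 for the 369 other rises and -0.548 for the falls, and 111 of these rises and 67 of the falls were at least 2-fold. An unadjusted p under 0.05 was reached by 540 genes without a block, and DESeq2 called 38 higher and 5 lower. Those 540 are under a 0.05 share of the 23777 genes tested, the share that p-values give on average where nothing changes. The same holds for the unadjusted counts of PtrSND1-B1 effects given below, so these counts add no evidence of further changes. They do not show an absence of further changes either. With the number block such genes numbered 1313, 913 and 677 at 7, 12 and 25 h, over that share at 7 h only. In the paired fit they numbered 3827, 3400 and 1949, over that share at each time. Without sGFP replicate 1, 2 or 3 the count of 14 became 3, 2 or 4, without PtrSND1-B1 replicate 1, 2 or 3 it became 2, 4 or 11, and with only the 7 h libraries in the fit it became 5. POPTR_0010s25450.1 passed the threshold without PtrSND1-B1 replicate 3 but not without any of the other 5 libraries, where its adjusted p was 0.0557 to 0.149, nor with only the 7 h libraries (adjusted p = 0.241). Its log2 fold change was 6.74 to 7.03 in 4 of these 5 omissions and 9.21 without sGFP replicate 3, which is no exact fold because the remaining control libraries held 0 reads.

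At 12 h, 2 genes were higher in PtrSND1-B1 protoplasts and 0 were lower by edgeR's test. They were the transfected gene and POPTR_0007s14780.1, which rose from 1.6 ± 0.34 to 26.1 ± 12.5 CPM (SD, n = 3), a log2 fold change of 3.99 (SE 0.546, edgeR adjusted p = 0.0222). For POPTR_0010s25450.1 the levels were 0.177 ± 0.154 CPM in sGFP and 5.66 ± 2.59 CPM in PtrSND1-B1 libraries. That difference did not pass without a block (adjusted p = 0.291) and passed with the replicate number as a block (0.00386) and in the paired fit (0.000105). With the number block 10 genes were higher and 4 lower, and in the paired fit 116 were higher and 184 lower. This paired total became 32, 63 or 79 without the replicate 1, 2 or 3 pair, 1069 with only the 12 h libraries and 1011 without the low-count filter (293 higher and 718 lower). With library size alone as the scaling the paired split was 144 higher and 149 lower. An unadjusted p under 0.05 was reached by 326 genes without a block, and DESeq2 called 9 higher and 3 lower. The count of 2 became 1 without any single sGFP library, or without PtrSND1-B1 replicate 1 or 2, because POPTR_0007s14780.1 then had an adjusted p of 0.0741 to 0.284. It became 0 with only the 12 h libraries in the fit.

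At 25 h the transfected gene was the 1 gene called higher and 0 were lower by edgeR's test. POPTR_0007s14780.1 was at 8.5 ± 4.94 CPM in PtrSND1-B1 against 0.607 ± 0.412 CPM in sGFP libraries (SD, n = 3), a log2 fold change of 3.66 (SE 0.642, edgeR adjusted p = 0.399). This difference passed with the replicate number as a block (adjusted p = 2.88e-05) and in the paired fit (1.41e-05). POPTR_0010s25450.1 was at 1.34 ± 1.39 against 0.203 ± 0.227 CPM and did not pass in any of the 3 fits, with a paired adjusted p of 0.12. The number block called 2 genes higher and 0 lower, and the paired fit called 37 higher and 68 lower. An unadjusted p under 0.05 was reached by 288 genes without a block and 677 with the number block, and DESeq2 called 3 higher and 1 lower. Exchanging the labels of the 25 h replicate 3 pair gave 188 paired calls, more than the labels as given. The total of these paired calls became 2 without the replicate 1 pair, 63 without the replicate 2 pair and 384 without the replicate 3 pair. It was 2 with only the 25 h libraries and 534 without the low-count filter, and the single call without a block was lost with only the 25 h libraries in the fit.

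**Figure D3:**
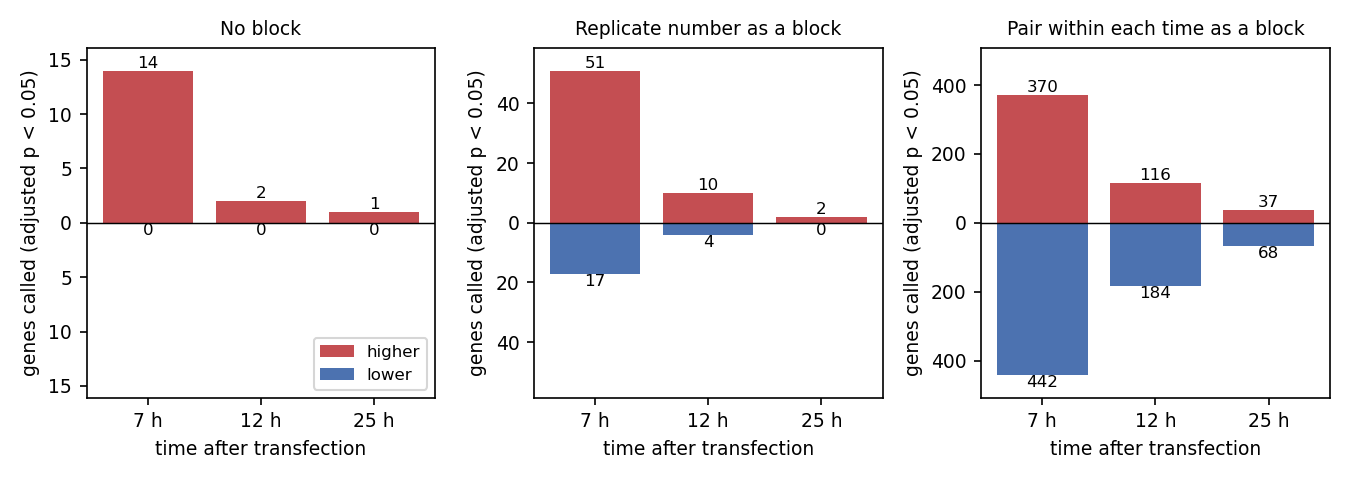
Genes called higher (red, upward) and lower (blue, downward) in PtrSND1-B1 than in sGFP protoplasts at 7, 12 and 25 h, in the fits without a block, with the replicate number as a block and with each pair of libraries as a block; each panel has its own axis. At 7 h the 3 fits called 14, 68 and 812 genes.

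Over the mean of the 3 times, 32 genes were higher and 6 lower in PtrSND1-B1 protoplasts by edgeR's test. The 31 rises besides the transfected gene ranged from 0.64 to 5.35 on the log2 scale (median 2.38), and 29 of them were at least 2-fold. The 6 falls ranged from -0.68 to -1.49 (median -0.764). With the replicate number as a block the counts were 110 higher and 113 lower. In the paired fit they were 929 higher and 1139 lower, among them all 38 genes called without a block, and 177 of the 2068 changes were at least 2-fold. The count of 38 fell by over 1.5 times without sGFP 7 h replicate 1 or 2 (23 and 25), sGFP 25 h replicate 1 or 2 (22 and 24), PtrSND1-B1 7 h replicate 1 (25) or PtrSND1-B1 25 h replicate 1 (23). The paired count of 2068 fell likewise without the 12 h replicate 1 pair (1277) or replicate 3 pair (1375), or the 7 h replicate 2 pair (1189) or replicate 3 pair (1335).

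The genes called at different times overlapped. Without a block, the 1 gene called at 12 h besides the transfected gene was among the 13 others called at 7 h, and the gene called at 25 h was the transfected gene. In the paired fit, 71 genes were higher and 133 lower at both 7 and 12 h, where independent lists would share 1.81 and 3.42. At 7 and 25 h, 21 higher and 34 lower genes were shared, against 0.576 and 1.26. At 12 and 25 h, 24 higher and 36 lower genes were shared, against 0.181 and 0.526. The largest adjusted p of these 6 paired overlaps was 9.4e-29 (Fisher's exact test, Benjamini-Hochberg over 9 overlaps). The control libraries of each time were separate. The lists still come from the same fit with a single spread per gene, while Fisher's test takes all genes as equally easy to call. These p-values therefore do not measure a shared response alone. Of 948 genes called at any time in the paired fit, 50 were called at all 3, of which 20 were higher and 30 lower at each time. Of the paired calls at 7 h, 94.6% of rises and 98.2% of falls had the same direction at 12 h, and 78.9% and 87.6% at 25 h. Without a block, 12 of the 13 other genes that rose at 7 h were also above 0 at 25 h, with a median of 1.87 against 4.41. A smaller value at the other time goes in part with the choice of genes. The paired rises at 25 h besides the transfected gene had a median of 1.71 there and 0.641 at 7 h. For the paired falls at 25 h these medians were -0.756 and -0.42.

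Differences of the PtrSND1-B1 effect between times were tested directly. Without a block 0 genes differed between 7 and 12 h, 12 and 25 h, or 7 and 25 h by edgeR's test. Unadjusted p-values under 0.05 numbered 108, 131 and 227, and DESeq2 called 0, 0 and 3. With the replicate number as a block 1 gene differed between 7 and 25 h, and the paired fit called 16, of which 14 had a lower effect at 25 h. All 14 were called higher at 7 h, with a median effect of 1.06, and none was called at 25 h in the paired fit, with a median of -0.15. These values follow in part from the choice of the 16 genes by that same difference. The other 2 were called lower at 7 h. For POPTR_0007s14780.1 the effect at 25 h minus that at 7 h was -1.99 (SE 0.93, edgeR adjusted p = 1), and -1.77 (SE 0.495, adjusted p = 0.313) in the paired fit. The count of 16 was 409 without the 25 h replicate 3 pair, of which 288 had a higher effect at 25 h, and 4 without the 7 h replicate 1 or 2 pair. It was 8 and 6 without the 25 h replicate 1 or 2 pair, 8 with RLE, 319 without the low-count filter and 31 with library size alone as the scaling (10 higher and 21 lower).

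**Figure D4:**
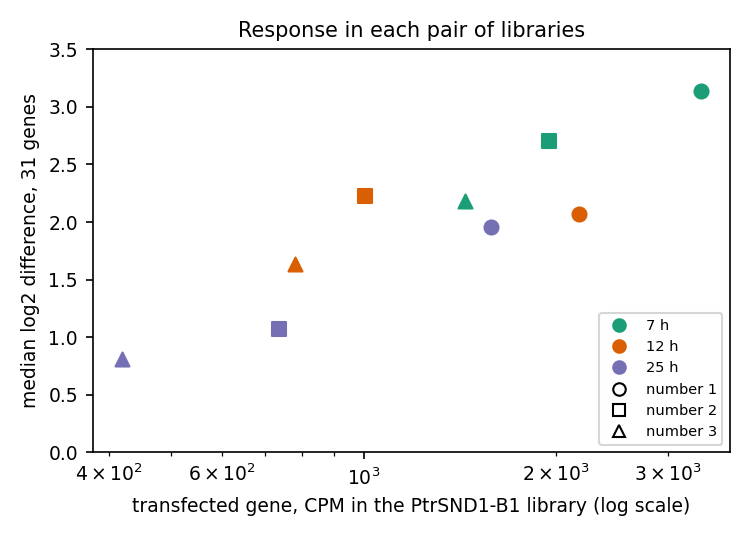
Median log2 difference between the PtrSND1-B1 and the sGFP library of each pair over the 31 genes called higher over the mean of the 3 times, against the CPM of the transfected gene on a log axis (colour, time; symbol, replicate number). The 9 pairs run from 0.808 at 418 CPM (25 h, replicate 3) to 3.14 at 3372 CPM (7 h, replicate 1).

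Those 31 genes were followed pair by pair. Their median log2 difference was 2.67 ± 0.481 (SD, n = 3 pairs) at 7 h, 1.98 ± 0.305 at 12 h and 1.28 ± 0.604 at 25 h. The difference between 25 and 7 h had an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 pairs allow. Inside numbers it was -1.18, -1.63 and -1.37 for replicates 1, 2 and 3, with an exact permutation p of 0.00926 over 216 exchanges of the times. The 6 genes called lower had medians of -0.883 ± 0.172, -0.873 ± 0.135 and -0.672 ± 0.0564 (SD, n = 3 pairs), and between 25 and 7 h the exact permutation p was 0.2 (0.13 inside numbers). Over the 9 pairs, the median of the 31 genes correlated with log2 CPM of the transfected gene, with Pearson's r = 0.906 (exact permutation p = 0.000791) and Spearman's rho = 0.8 (exact permutation p = 0.0138). This relation was seen before it was tested. Without the 2 pairs farthest from the median CPM, r was 0.738, and with the mean of each time removed it was 0.849 (exact permutation p = 0.0278 over 216 arrangements). With only the mean of each replicate number removed r was 0.927 (exact permutation p = 0.00926 over 216 arrangements), and with both sets of means removed it was 0.00678, with 4 residual degrees of freedom. The replicate 3 pair was the lowest in both measures at all 3 times.

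The sGFP protoplasts give the change with time after transfection without PtrSND1-B1. From 7 to 25 h, 2065 genes rose and 2191 fell by edgeR's test, with medians of 1.39 and -1.26 on the log2 scale, and 1477 and 1371 of them changed at least 2-fold. The 2 largest falls without a block among genes that met the rule for named genes were those of POPTR_0014s11370.1 and POPTR_0005s15100.1. POPTR_0014s11370.1 fell from 17.2 ± 17.1 to 0.439 ± 0.38 CPM (SD, n = 3), a log2 change of -4.91 (SE 0.978, edgeR adjusted p = 0.00303), and of -3.69 (adjusted p = 0.0173) without 7 h replicate 2. POPTR_0005s15100.1 fell from 8.63 ± 4.88 to 0.314 ± 0.322 CPM, a log2 change of -4.53 (SE 0.944, edgeR adjusted p = 0.00406). Their order turns with the replicate number as a block (-4.33 and -4.63) and without sGFP 7 h replicate 2 (-3.69 and -4.84). Neither differed between PtrSND1-B1 and sGFP protoplasts at any single time in the 3 fits, but over the mean of the 3 times POPTR_0005s15100.1 was higher in the paired fit, with a log2 fold change of 1.22 (SE 0.242, edgeR adjusted p = 0.00585). From 7 to 12 h, 36 genes rose and 19 fell, and from 12 to 25 h 107 rose and 56 fell. With only the groups of the contrast in the fit, 0 genes were called over either of these spans. With the replicate number as a block the counts were 688 and 846 from 7 to 12 h, 1056 and 1164 from 12 to 25 h, and 3628 and 3956 from 7 to 25 h. With library size alone as the scaling, which moved the median of all genes by -0.169 from 7 to 25 h, 1292 genes rose and 2887 fell over that span, and from 12 to 25 h 76 rose and 80 fell. From 7 to 25 h the count of 4256 was 2763 without sGFP 7 h replicate 1, 2810 without 7 h replicate 2 and 2704 without 25 h replicate 1. The 55 genes of 7 to 12 h were 0, 3 and 0 without 7 h replicate 1, 2 or 3, and 4, 7 and 17 without 12 h replicate 1, 2 or 3, and the 163 of 12 to 25 h were 65, 67 and 46 without 12 h replicate 1, 2 or 3, and 35 and 90 without 25 h replicate 1 or 2.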

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

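The fit that pairs libraries within each time was chosen after seeing the data. Of the tests in this part, those of the spread between libraries, of the level of the transfected gene and of exchanged labels in a pair were chosen only after the result was seen. The criteria for the spread under pairing and for the transfected gene were tightened after their values were seen. By its first criterion the spread under pairing would have counted as support, as would the spread at 25 h, and scaling would have counted as argued against, before limits of these tests were noticed.

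A difference between times drew attention to 2 results. The PtrSND1-B1 effect differed between 7 and 25 h for 16 genes in the paired fit, and with the replicate number as a block for 1 gene, against 0 without a block by edgeR's test (227 at an unadjusted p under 0.05, 3 by DESeq2). Of the 10 ways to divide the 6 pairs of these times, 2 gave 16 or more calls, and the highest other gave 811 by placing 7 h replicate 1 with 25 h replicates 1 and 2. The splits are too few for a share under 0.05, and a count so far above the real one points to a structure of the pairs other than time. The 16 were 409 without the 25 h replicate 3 pair, 8 and 6 without the 25 h replicate 1 or 2 pair, and 4 without the 7 h replicate 1 or 2 pair.

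The first pattern weighed is that far more genes were called, with falls among them, once libraries were paired within each time. Scaling of the libraries stays open as the source of the falls at 7 h. RLE or library size alone moved the share of falls, 54.4%, by at most 2.44 percentage points. They moved the median of all genes by only -0.00768 and 0.0132, too little for a test. Falls numbered 447 with RLE and 456 with library size alone, against 442, so they did not hang on the choice among these scalings. An error shared by all of these scalings was not tested. Part of the spread of the unpaired fit lies between replicate numbers, since with the number alone as a block the coefficient of variation was 0.662 of the unpaired value. Whether this accounts for the larger count stays open by the criterion used. In the paired fit the coefficient of variation was 0.272 of the unpaired value, which restates the larger count. Whether a number marks a protoplast isolation, a day or a library batch stays open, because the labels do not say, and no biological explanation was tested.

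The second pattern is that fewer genes were called at 25 h than at 7 h in the paired fit (37 higher and 68 lower, against 370 and 442). Depth is argued against, since after thinning to equal totals the median ratio of the counts was 10.9 (7.69 to 11.2 over 5 draws). A wider spread between pairs at 25 h stays open: fitted alone, 25 h had a coefficient of variation 1.61 times that at 7 h (10.7% against 6.63%), from the same fits that called 1190, 1069 and 2 genes at 7, 12 and 25 h, but the paired fit takes a single spread per gene over the times and its median SE at 25 h was 1.04 times that at 7 h. Less transfected transcript cannot be told apart from time itself, since its level and the response were both lower at 25 h in each number (r = 0.927 within numbers, 0.849 within times, 0.00678 with both sets of means removed). A smaller effect of PtrSND1-B1 at 25 h stays open as a biological explanation, and the counts are weak evidence for it, since in separate fits, each without 1 pair, they were 2, 63 and 384 at 25 h without its replicate 1, 2 or 3 and 470, 248 and 349 at 7 h without its replicate 1, 2 or 3.

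The third pattern is that exchanging the labels of the 25 h replicate 3 pair gave 188 paired calls at 25 h, more than the 37 rises and 68 falls of the labels as given. Exchanged labels in that pair are argued against, since the transfected gene was 200 times higher in its PtrSND1-B1 library than in its sGFP library, and the other 8 pairs alone single out the same gene (mean log2 difference 8.19, against 4.3 for the next). Unequal depth inside the pair is argued against too, since after thinning the exchange still gave 4.82 times as many calls in the median draw (3.52 to 6.56). Over all genes the log2 differences of this pair correlated with those of 25 h replicates 1 and 2 at 0.0617 and -0.015, and with those of the 7 and 12 h pairs at 0.0935 to 0.224, while for 25 h replicate 2 the correlations with the 7 and 12 h pairs were -0.00911 to 0.15. What parts the 25 h pairs stays open, and no biological explanation was tested.

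Other divisions of the libraries were counted for each result. Without a block, 1 of the 10 splits of the 6 libraries, the real one, gave as many calls at 7 h (14), 12 h (2) and 25 h (1), and in sGFP protoplasts from 7 to 12 h (55), 12 to 25 h (163) and 7 to 25 h (4256). The highest other was 0 each time, also among the 4 splits that part all pairs. Of the 4 exchanges of labels inside pairs, 1 gave in the paired fit as many at 7 h (812, highest other 0) and at 12 h (300, highest other 0), and 2 of 4 at 25 h (37 higher and 68 lower, highest other 188). All of these are too few for a share under 0.05.

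Over the mean of the 3 times without a block, 3 of 100 splits inside times gave at least the real 38 calls, the real split among them. That share is under 0.05, but these 100 are a random sample of the splits and take no account of the pairing, so chance is not excluded by it. The highest other, 2931, and the next, 1661, group libraries by replicate number, a structure of the samples, and part 3 of the 9 pairs each. Among 100 arrangements that part all 9 pairs, 1 gave as many, the real one, and the highest other gave 11. For the paired fit, 2 of 100 exchanges gave at least the real 2068, and the highest other, 2091, came from exchanging 25 h replicates 1 and 2. The share of 2 in 100 is also under 0.05, again from a random sample of the arrangements. The count leaned on the 25 h labels unevenly. Exchanging 25 h replicate 2 alone left 1697 calls, and exchanging 25 h replicate 3 alone left 837. Exchanging 25 h replicates 2 and 3 left 269, and exchanging all 3 pairs of 25 h left 198. For the differences of the effect between 7 and 12 h, 12 and 25 h, and 7 and 25 h, the real count was 0 (108, 131 and 227 at an unadjusted p under 0.05; 0, 0 and 3 by DESeq2), so all 100 of 100 splits were bound to be as large and the comparison says nothing about chance. The highest others were 1053, 2051 and 8458, from splits that exchange time labels inside each construct. Which libraries these splits placed together was not kept, so no structure of the samples is read from them.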

How the results depend on the processing

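The paired fit, its alternatives and the use of all models were chosen after seeing the data. No named gene changed direction. For the named genes, 112 of 126 alternative values stayed on the same side of the threshold and 14 fell below it. Of the counts, 155 of 261 stayed within 1.5 times. These 155 include counts that were 0 both times, from the differences of the effect between times, which were 0 without a block. They also include the 1 call at 25 h, the transfected gene, where it stayed at 1. Such cases are no sign of stable counts, so the 155 overstate the stability. The cause of the moves was not tested, except that a fit of only the groups of a contrast, or without a library, holds fewer libraries. The planned gene list tests were not run because no list had members, and those for normalized values did not apply to counts. The random splits over the mean of the 3 times were drawn again with another seed, and that draw held no other split as large; the first draw is the one given.

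The replicate number as a block gave 68, 14 and 2 calls at 7, 12 and 25 h (14, 2 and 1 without it), 223 over the mean (38) and 1 for the difference from 7 to 25 h (0). Overlaps between times were 13, 2 and 2. In sGFP protoplasts it gave 1534, 2220 and 7584 (55, 163 and 4256). The within-time replicate block, the paired fit, gave 812 at 7 h, 300 at 12 h, 37 higher and 68 lower at 25 h, then 2068 over the mean and 16 for the difference, with overlaps of 204, 55 and 60. Neither changed another count by over 1.5 times.

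The likelihood ratio test gave 50, 15 and 4 at the 3 times, 106 over the mean, 3 for the difference, and 374 and 580 in sGFP protoplasts from 7 to 12 and 12 to 25 h. DESeq2 gave 43, 12 and 4, then 106, 3, 416 and 597, with overlaps of 11, 4 and 4. With only the groups of a contrast in edgeR the counts were 5, 0 and 0, and 0, 0 and 2428 in sGFP protoplasts. Without the low-count filter 24 genes were called from 7 to 12 h, and at an adjusted p under 0.01 the 7 and 12 h overlap was 1. In the paired fit a 2-fold minimum gave 179, 87, 44, 177 over the mean and 10 for the difference. Without the filter it gave 1539, 1011 and 534, and 319 for the difference, which was 8 with RLE and 31 with library size alone. Library size alone moved the shares of rises and falls over 10 points from 7 to 25 h (1292 and 2887, against 2065 and 2191), 12 to 25 h (76 and 80, against 107 and 56), in the paired 12 h calls (144 and 149, against 116 and 184) and in the paired difference (10 and 21, against 2 and 14). With only the libraries of 1 time the paired counts were 1069 at 12 h and 2 at 25 h.

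The larger direction turned in 23 counts that held at least 10 genes under the alternative, whatever the size of the first count. At 12 and 25 h only 2 and 1 genes were called without a block, too few for a larger direction to be read. The blocks did this at 7, 12 and 25 h (paired), over the mean, and from 7 to 12 and 12 to 25 h in sGFP protoplasts (number). Rises outnumbered falls among paired calls with a 2-fold minimum (112 and 67 at 7 h, 51 and 36 at 12 h, 26 and 18 at 25 h), over the paired mean with library size alone (1100 and 1006, against 929 and 1139), and without 7 h replicate 3 (178 and 171), 12 h replicate 1 (17 and 15) or 25 h replicate 3 (196 and 188, and 288 and 121 for the difference). From 7 to 25 h they did so with a 2-fold minimum (1477 and 1371), no filter (1959 and 1723), only these groups (1227 and 1201) or without sGFP 25 h replicate 2 (1713 and 1559) or 3 (1945 and 1852). From 12 to 25 h falls outnumbered rises with library size alone and without sGFP 12 h replicate 2 (36 and 31) or 3 (24 and 22).

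Without each library in turn the counts were 2 to 11 at 7 h, 1 to 2 at 12 h, 1 to 1 at 25 h and 22 to 55 over the mean, the 55 without sGFP 12 h replicate 3. In sGFP protoplasts they were 0 to 17, 35 to 192 and 2704 to 3797. Without each pair the paired counts were 248 to 470 at 7 h, 32 to 79 at 12 h, 2 to 384 at 25 h, 1189 to 1984 over the mean and 4 to 409 for the difference. The report names those that moved a count by over 1.5 times.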

Other observations

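The counts of neighbouring identifiers were chosen after the calls were seen. Over the mean of the 3 times in the paired fit, the 1139 genes lower in PtrSND1-B1 protoplasts held 306 pairs of loci whose identifiers lie within 50 of each other on the same scaffold. Random sets of tested genes held 152 on average and at most 190 (permutation p = 5e-04, the smallest that 2000 draws allow, also for the values below). The 929 higher genes held 143 such pairs, against 102 and at most 135. In sGFP protoplasts from 7 to 25 h the 2065 rising genes held 646, against 478 and at most 540, and the 2191 falling genes 727, against 534 and at most 600. Reads shared between close copies were not separated.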
